A study of Mus musculus with 15 samples.

How the data were processed

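The series holds 15 arrays of mouse liver RNA (strain C57BL/6), 3 for each of 5 stages: E12.5, E14.5, E17.5, neonatal and adult (8 weeks). Stages and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol, ribosomal RNA was removed with an mRNA isolation kit, and random-primed Cy3 cRNA covering whole transcripts was hybridised in 1 colour. Per the file headers, the arrays are Agilent arrays with a probe grid built on mm9, read with Feature Extraction 11.0.1.1 and its 1-colour protocol, whereas the submitters' processing notes name Feature Extraction 10.7.3.1; which of them made the deposited values is not known. Per the file headers, the spot intensity values are on a linear scale, background-subtracted and spatially detrended by the scanner software, with no scaling between arrays. The arrays fell into 2 scans with no array position repeated within a scan, of 8 and 7 arrays, and each scan was taken as 1 slide; slide and scan are therefore 1 batch here. Per the file headers, the software applied a multiplicative detrending step on the second-slide arrays except adult replicate 2 and on no first-slide array. The authors' value table holds log2 values of the same arrays. Its order of probes within each array matched the scanner values (Spearman 1 for all 15), and it was not centred by probe. In replicate order its column medians were 7.85, 7.88 and 7.88 at E12.5, 7.89, 7.89 and 7.89 at E14.5, 7.88, 7.89 and 7.87 at E17.5, 7.85, 7.84 and 7.85 in neonatal liver, and 7.80, 7.81 and 7.80 in adult liver. Scale (log2), centring and direction were thus settled from the values. Its normalization and its filter are not given in the sources used here. Every probe in it was well above background on at least 12 arrays, and 30551 probes are not in it. Its highest value was 18.111 on each array except E14.5 replicate 3 (17.837). Quantile normalization also gives arrays shared values, so the authors' table may not be a scaling separate from that setting.

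Each array had 62513 spots, of which 59994 were noncontrol and 1200 belonged to 20 negative-control probes. Control spots and outlier spots marked by the scanner software were left out, spots of the same probe were averaged (15 probes had 20 spots each), and log2 of the processed signal minus the array's own 75th percentile over all noncontrol probes was the main setting, since on the median array 58.1% of probes were well above background. Of 59709 probes, 123 carried a RefSeq accession. These were looked up without versions in the reference gene tables (assembly GRCm38.p6, used for names only), which gave 116 of them 112 current symbols and left 7 unmatched. The files do not pair the other probes with genes, and they keep the files' IDs: 5365 with lincRNA names, 962 for ultraconserved elements, 1417 with another accession and 51842 with the maker's ID alone. NM accessions were counted as coding, NR accessions and lincRNA names as noncoding, and the rest as unclassified. For the 3 symbols with several probes the brightest probe stood for the gene. Features well above background on all 3 arrays of at least 1 stage were tested, 37357 of 59705, among them 77 coding and 2533 noncoding ones and 231 with a missing value. No coordinates are given, because the reference tables are on another build than the arrays. The 37 symbols that were not tested are mostly Y-linked, germ line and vomeronasal receptor genes.

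Signal over background stands for depth here. On 14 arrays between 50.9% and 62.9% of noncontrol spots were well above background, and 80.9% on E17.5 replicate 1, where 55.8% of negative-control spots were also well above background, against 4.0% to 9.58% elsewhere. The 75th percentile of the signal ranged from 150 to 309 between arrays and the median from 26.4 to 83.4. A feature that was not well above background on any array of a stage has only a bound there. Its fold is given as at least the bright stage's mean over the dim stage's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. The adjusted p beside such a bound is limma's for the unbounded difference. On each E12.5 array Amy2a5, Csprs, Vmn1r111 and Vmn1r157 shared the same value. Their SD at E12.5 (0.47) is therefore not a spread measured for each gene.

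Differences were tested with limma (version 3.58.1, lmFit and eBayes, two-sided) in R 4.3.3, in 1 fit over all 15 arrays with a mean per stage and no block. P-values were adjusted by Benjamini-Hochberg per comparison, and a feature was called at an adjusted p below 0.05, with the number changed at least 2-fold beside it. A moderated F test covered all 5 stages. The design, the alternatives, the 35 gene lists and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 5 coding features up and 5 down and the 3 noncoding up and 3 down with the largest log2 fold change among called features with a symbol that were well above background on all 6 arrays and whose stages did not overlap (which chance gives in 1 of 10 splits), plus the 2 brightest coding bounds and up to 4 called members of each described list. Lists with at least 5 measured members were tested with camera (preset correlation 0.01, and an estimated correlation as an alternative), adjusted over all lists and comparisons. The lists with measured members were erythroid maturation, cholesterol synthesis, exocrine pancreas and housekeeping genes; the other 31 had no member under a gene symbol among the tested features. Further gene groups (histone H2A, chemokines and immune surface genes, vomeronasal receptors, germ line and early embryo genes, cell machinery, and genes spotted 20 times) were drawn from the arrays' annotation after the array-wide quality values and before any gene's values were looked at. Shares of noncoding calls were set against 10000 random sets of the same size, drawn from the other tested features and matched on mean signal.

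The procedure was tested on simulated data for adult versus E12.5, with 200 of 37357 features changed. At a log2 change of 2 it recovered 52% with a median estimate of 2.05, and at a log2 change of 1 it recovered 2% with a median estimate of 1.02. Of 57 calls 3 were false (5.26%). As so few features were changed there, the adjusted threshold was stricter than in the data, where 18978 features were called in this comparison, and the shares recovered do not carry over to it.

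Alternatives were quantile normalization, the 75th percentile over the probes well above background on all arrays, normexp background correction (offset 50), the authors' table, no filter or a stricter filter on dim probes, the mean over a gene's probes, only the 2 stages compared in the fit, the replicate number or the slide as a block, an intensity trend in eBayes, an adjusted p below 0.01, and leaving out each array in turn. The files hold no mean spot signal, so normexp used the median spot and background signals. Added after the data were seen were fits without E17.5 replicate 1 for every comparison, a background set from the negative-control probes (floor 0.025 of the array's 75th percentile) and fits within a slide. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 read the files, and matplotlib 3.10.9 drew the figures.

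The scale of the arrays matters for directions. Medians given below for the authors' table cover only the tested features that it holds. The median log2 difference of all tested features moved beyond 0.1 in some settings: at E17.5 versus E14.5 to −0.15 after quantile normalization, −0.126 with the negative-control background and −0.158 in the authors' table; at neonatal versus E17.5 to −0.16 with the percentile over detected probes; and at adult versus E12.5 to −0.124 after quantile normalization and −0.18 in the authors' table. At adult versus neonatal it was 0.168 in the main setting and between 0.063 and 0.202 in the others. A fold change is therefore relative to the array's own 75th percentile.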

Results

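Gene expression was measured in livers of C57BL/6 mice, an inbred laboratory strain, at 5 stages: embryonic days E12.5, E14.5 and E17.5, newborn (neonatal) and adult at 8 weeks. The embryonic liver is a site of blood cell formation, and the organ takes on its adult metabolic functions around and after birth. Each stage had 3 arrays, 15 in all. The stated aim was to profile mRNAs and long noncoding RNAs (lncRNAs) over this course, so the comparisons made here are the 4 steps between neighbouring stages, the adult against the first stage, and a test over all 5 stages. Of 59709 probes, 37357 features were well above background on every array of at least 1 stage and were tested. A gene symbol could be given to 112 genes, of which 75 were tested, 72 coding and 3 noncoding. Another 5365 probes carried lincRNA names (long intergenic noncoding RNAs) and 962 carried the names of 481 ultraconserved elements, genome segments that are identical between distant mammals; the files do not pair these or the 51842 probes known by the maker's ID with genes. Fold changes below are differences of log2 signal with their standard errors (SE) and limma's adjusted p, with 3 arrays per stage, and the number of arrays limits their precision. The labels do not say whether the 3 arrays of a stage came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

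The arrays followed the order of development. Principal component 1, with 54.3% of the variance, ran from E12.5 through E14.5, E17.5 and neonatal to adult liver, and on component 2, with 15.4%, the neonatal arrays lay between −129.92 and −114.43, E17.5 replicate 3 at −87.07 and the other 11 arrays between −1.96 and 107.26. Across features, the median correlation between arrays of 1 stage was 0.984 at E14.5, 0.980 in neonatal liver, 0.981 in adult liver, 0.952 at E12.5 and 0.940 at E17.5. Between stages it was 0.952 for E12.5 and E14.5, 0.949 for E14.5 and E17.5, 0.915 for E17.5 and neonatal, 0.891 for neonatal and adult, and 0.769 for E12.5 and adult liver, so by this measure E12.5 and E14.5 were about as alike as the arrays within E12.5. The medians with E17.5 mix pairs on 1 slide and pairs across slides. On 1 slide the E17.5 pair correlated at 0.9645, against 0.947 to 0.9591 for E14.5 with E17.5. Across slides the E17.5 pairs were at 0.938 and 0.9401, against 0.9225 to 0.9308. Held apart in this way, E17.5 arrays were more alike than E14.5 and E17.5. Across slides, E17.5 replicates 1 and 2 correlated at 0.9035 to 0.9201 with the neonatal arrays, below the E17.5 pairs. On its own slide, however, E17.5 replicate 3 correlated at 0.9464 to 0.956 with the neonatal arrays, above its values with the other E17.5 arrays. That slide held no E17.5 pair, so stage and slide were not held apart there. The E12.5 and E14.5 arrays and E17.5 replicates 1 and 2 lay on 1 slide, and E17.5 replicate 3 lay with the neonatal and adult arrays on the other. Stage and slide can therefore be separated only through E17.5 replicate 3, and values with the slide as a block or within a slide stand beside each comparison below. The block sets that array against E17.5 replicates 1 and 2. Replicate 1 had raised signals in dim probes, and no fit with the block left it out.

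**Figure D1:**
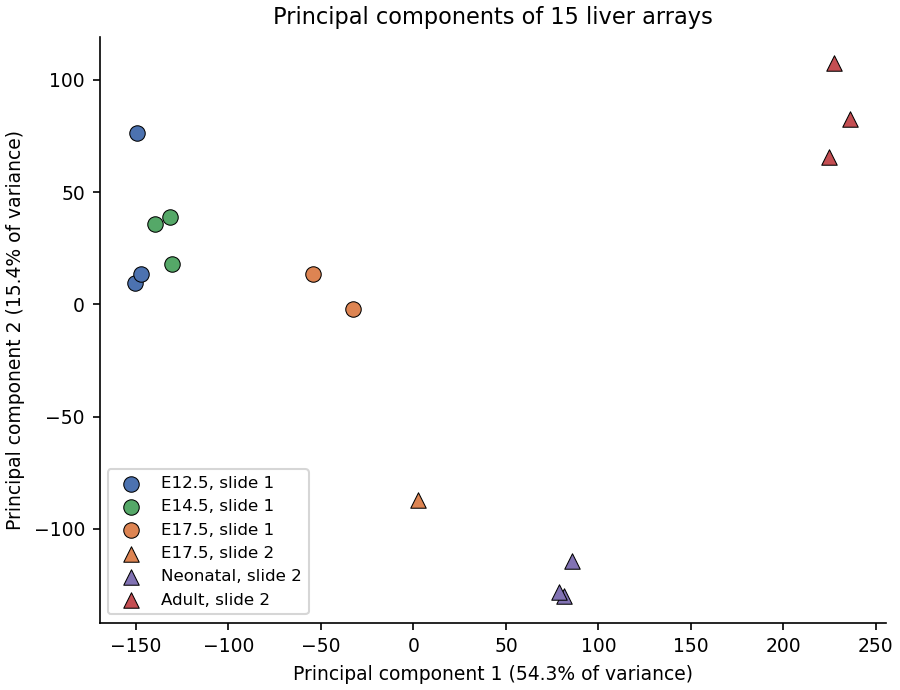
Principal components 1 (54.3% of variance) and 2 (15.4%) of the log2 signals of 15 arrays, coloured by stage, with circles for the first slide and triangles for the second. E17.5 replicate 3, on the second slide, lies nearer to the neonatal arrays than E17.5 replicates 1 and 2 on the first.

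The step from E12.5 to E14.5 addressed the change in the liver during the embryonic blood-forming period. Amy2a5, a pancreatic alpha-amylase gene, rose at least 5.82-fold (adjusted p = 2.02e-06 for the unbounded difference): it was not well above background on any E12.5 array and well above it on all 3 at E14.5. Normexp background correction, whose added offset compresses dim signals, gave a log2 change of 1.72, still called but below that bound. The mouse genome holds near-identical amylase copies, so the signal was not assigned to 1 of them. Small decreases were called for Disp1, which encodes a protein needed to release Hedgehog signals (log2 change −1.08 ± 0.28, adjusted p = 0.0457), for Gm13305 (−1.14 ± 0.31, adjusted p = 0.0492) and for Ppp2r3d, which has a noncoding RefSeq accession here (−1.09 ± 0.28, adjusted p = 0.0376). Hhipl2, named after its values were seen because it completes the 5 called symbols, was called lower (adjusted p = 0.033), but it was well above background on 2 arrays at E12.5 and none at E14.5, so no fold is given. Transferrin receptor Tfrc, which imports iron and is abundant in red cell precursors, and Hmgcs1, the cytosolic HMG-CoA synthase of cholesterol synthesis, were not called, with log2 changes of −0.02 ± 0.34 and 0.33 ± 0.28. Among lincRNA exon probes 14 rose and 75 fell, but 70 rose and 72 fell without E12.5 replicate 1, and leaving out any other array of these stages gave 2 to 9 up. Normexp gave 53 up and 101 down, values from the authors' table gave 29 and 67, and the slide as a block 33 and 100. The called probes named for mouse lincRNAs numbered 5, all up. Under the other scalings 4 to 6 were called, with the block 10 and on leaving out 1 array 0 to 12, none of them down. Those named for human lincRNAs rose in 3 of 3, with 1 falling under quantile normalization, normexp, the authors' table and the block and without E12.5 replicate 3, and 10 rose without E12.5 replicate 1.

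In all, 1843 features changed between E12.5 and E14.5 (4.93% of those tested), 680 up and 1163 down, and 1720 of them changed at least 2-fold. Of 2533 noncoding features 98 changed, 22 up (22.4% of the calls) and 76 down. The up share among noncoding calls was 38.3% after normexp background correction and 34.3% in the authors' table. Within the first slide, which held both stages, 1295 features were called, and 2601 with the slide as a block. Leaving out E12.5 replicate 1 turned the balance to 1409 up and 1194 down among all features, 92 up and 72 down among noncoding ones and 13 up and 10 down among ultraconserved elements (3 up and 7 down with all arrays). Without E12.5 replicate 3, E14.5 replicate 1 or E14.5 replicate 3 the total was 1013, 673 or 817. Noncoding calls then numbered 58, 32 or 40, and the rise of mouse lincRNAs fell to 0 calls without E14.5 replicate 1. The calls of the 3 small decreases were lost on leaving out any 1 of the 6 arrays, and within the first slide those of Disp1 (adjusted p = 0.0756) and Ppp2r3d (0.0933). For Disp1 the adjusted p was 0.0892, 0.0534 and 0.127 without E12.5 replicates 1, 2 and 3, and 0.203, 0.0578 and 0.175 without those of E14.5 (range over its alternatives 0.0143 to 0.203). For Gm13305 these were 0.0892, 0.0702 and 0.138, and 0.22, 0.0689 and 0.165 (range 0.0126 to 0.22), and for Ppp2r3d 0.0684, 0.0542 and 0.113, and 0.139, 0.0564 and 0.18 (range 0.0138 to 0.18).

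Between E14.5 and E17.5, the last part of gestation, the change was mostly upward. Amy2a5 rose a further 70.5-fold (log2 change 6.14 ± 0.30, adjusted p = 1.68e-07). H2ac18, a core histone H2A gene, rose 4.59-fold (2.20 ± 0.24, adjusted p = 7.09e-05), and Gk, glycerol kinase, which brings glycerol into metabolism, rose 2.48-fold (1.31 ± 0.29, adjusted p = 0.0157). Gm4312 fell by 1.02 ± 0.24 on the log2 scale (adjusted p = 0.0193). Csprs, the fifth symbol called and named after its values were seen, was called higher (adjusted p = 0.000271), from no array well above background to 2 of 3, so no fold is given. Tfrc (−0.28 ± 0.34, adjusted p = 0.667) and Hmgcs1 (0.54 ± 0.28, adjusted p = 0.282) were again not called. Of the lincRNA exon probes called, 123 rose and 14 fell, and more rose than fell under every scaling. The called human lincRNA probes (19 up, 2 down) and mouse lincRNA probes (8 up, 2 down) rose more often than they fell in the main scaling, but the balance turned to 5 up and 9 down and to 3 up and 5 down after quantile normalization, and was also turned in the authors' table and with the background set from negative-control probes (for mouse lincRNAs, with normexp too). Called ultraconserved element probes rose in 20 of 22, which became 7 up and 9 down after quantile normalization. The median over all noncoding features was −0.08, opposite in sign to most of the calls.

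In all, 2656 features changed between E14.5 and E17.5, 2352 up (88.6%) and 304 down, with 2457 at least 2-fold. Noncoding calls numbered 168, 150 up (89.3%) and 18 down. Quantile normalization, normexp and the authors' table gave up shares of 73.3%, 71.5% and 71.5% over all features, and 65.2%, 69.4% and 71.4% over noncoding ones, with 71.2% for noncoding features when the background was set from negative-control probes. Within the first slide 1410 features were called, of them 64 noncoding, and 2982 and 148 with the slide as a block. H2ac18, Amy2a5, Gk and Gm4312 changed by 2.16, 6.21, 1.28 and −1.20 with the block and kept their calls. The totals were 1380, 1422 and 1591 without E14.5 replicates 1, 2 and 3, and the noncoding counts 83, 81 and 99. Without E17.5 replicate 2 there were 263 noncoding calls. The call of Gk was lost without E14.5 replicate 1 (adjusted p = 0.0672) or 3 (0.0551; range over its alternatives 0.0094 to 0.0672). That of Gm4312 was lost without E14.5 replicates 1, 2 or 3 (0.082, 0.0768 and 0.0514) or E17.5 replicate 2 (0.056; range 0.00336 to 0.102).

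Around birth, from E17.5 to neonatal liver, Gk rose another 3.01-fold (log2 change 1.59 ± 0.29, adjusted p = 0.00253), H2ac18 rose by 0.95 ± 0.24 (adjusted p = 0.0155) and the noncoding RNA 4930526I15Rik rose by 1.36 ± 0.25 (adjusted p = 0.00263). Hmgcs1 fell 4.33-fold (−2.12 ± 0.28, adjusted p = 0.000305), the only measured member of the cholesterol synthesis list and the one of these 8 genes whose call held under every alternative, 2 of which rest on 1 E17.5 array. H2al2b, a histone H2A-like gene known from male germ cells, fell by 1.63 ± 0.31 (adjusted p = 0.00309). Vmn1r187 and Vmn1r257, vomeronasal pheromone receptors, and Ldhal6b, a lactate dehydrogenase A-like gene, had lower values by −2.37 ± 0.55 (adjusted p = 0.00967), −1.11 ± 0.35 (0.0434) and −2.14 ± 0.55 (0.0166), but the 3 arrays at E17.5 differed widely for them, with SDs of 1.38, 0.88 and 1.56. Amy2a5 was at its highest mean in neonatal liver (6.03 ± 0.46, SD, n = 3), 0.47 ± 0.30 above E17.5, a difference that was not called (adjusted p = 0.303), and Tfrc changed by −0.43 ± 0.34 (adjusted p = 0.403). Probes named for lincRNAs fell more often than they rose: 223 against 126 for lincRNA exons, 60 against 15 for human and 36 against 8 for mouse lincRNAs, and 39 of the 47 ultraconserved element probes called fell, in each family also under every other scaling. With a block for the slide this step is estimated from E17.5 replicate 3 alone, the E17.5 array nearest to the neonatal ones on principal component 1 (2.56, against −32.58 and −54.12), so the following values restate where that array lay. Calls down then numbered 50 against 35 up for lincRNA exons, 8 against 6 for human and 8 against 3 for mouse lincRNAs, and 13 against 2 for ultraconserved elements. The median changes of the 3 lincRNA families were −0.23, −0.40 and −0.54 with all E17.5 arrays, and 0, 0.02 and −0.01 with the block.

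In all, 6747 features changed at this step (18.06%), 3137 up and 3610 down, and 5662 at least 2-fold. The balance over all features turned to 53.8% up with normexp and 53.6% up with the background set from negative-control probes, and was 50.1% up without E17.5 replicate 1. Of 469 noncoding calls, 150 rose (32.0%) and 319 fell; the up share was 42.4% with the background set from negative-control probes. Within the second slide, which held E17.5 replicate 3 and the neonatal arrays, 2196 features were called, 111 of them noncoding (44 up, 67 down). With the slide as a block these numbers were 2265 and 110. In both, E17.5 was represented by that 1 array, which has no spread of its own and was assumed to vary like the other groups. Leaving out E17.5 replicates 1, 2 and 3 gave 4411, 3611 and 13309 calls, with 271, 210 and 1110 noncoding ones, and leaving out neonatal replicates 2 and 3 gave 3674 and 3726, with 242 and 252. Coding calls numbered 7, and 19 without E17.5 replicate 3.

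With the slide as a block, Hmgcs1 changed by −2.53 (adjusted p = 0.00167; 0.0144 within the second slide; range over its alternatives 6.75e-06 to 0.0144). Gk changed by 1.53 within the second slide, where its call was lost (adjusted p = 0.0979, against 0.0482 with the block; range 0.000252 to 0.0979). The block and the second slide gave 4930526I15Rik 1.19 (adjusted p = 0.0592 and 0.0936; range 0.000205 to 0.0936), H2ac18 0.87 (0.148 and 0.122; range 0.00105 to 0.148) and H2al2b −1.33 (0.0908 and 0.0878; range 0.000998 to 0.0908), none of them called. They gave Vmn1r187 −0.80 (0.461 and 0.17; range 0.000163 to 0.461), Ldhal6b −0.36 (0.721 and 0.649; range 3.51e-05 to 0.721) and Vmn1r257 −0.16 (0.911 and 0.869; range 0.000721 to 0.911), also without a call. Without E17.5 replicate 3, Vmn1r187 and Ldhal6b changed by −3.15 and −3.03, and with normexp by −1.33 and −1.51, all called, while Vmn1r257 lost its call with normexp (−0.50, adjusted p = 0.103). H2ac18 was further lost without neonatal replicate 2 (0.0689), Ldhal6b without E17.5 replicates 1 or 2 (0.0709 and 0.0803) or neonatal replicates 2 or 3 (0.0614 and 0.0564), and Vmn1r257 without E17.5 replicates 1 or 2 (0.119 and 0.197) or any neonatal replicate (0.0919, 0.0866 and 0.128).

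From neonatal to adult liver, Hmgcs1 rose 8.59-fold (log2 change 3.1 ± 0.28, adjusted p = 1.91e-06), to its highest mean of the 5 stages. Tfrc fell 6.33-fold (−2.66 ± 0.34, adjusted p = 4.7e-05) and Amy2a5 fell 13.6-fold (−3.77 ± 0.30, adjusted p = 5.35e-07). The chemokine genes Ccl21b (2.39 ± 0.38, adjusted p = 0.000348) and Ccl21c (1.63 ± 0.34, adjusted p = 0.00269), near-identical copies whose signals were not told apart, rose together with Gm13304 (2.44 ± 0.40, adjusted p = 0.00045). The means of Gm13304 and Ccl21b were close (0.15 and 0.06 in neonatal, 2.58 and 2.45 in adult liver), so Gm13304 may not be a separate signal. Vamp7, a vesicle fusion protein, rose by 1.44 ± 0.33 (adjusted p = 0.00531). Csprs rose at least 7.27-fold (adjusted p = 5.87e-06) from below the background limit on all neonatal arrays. Tuba1b, an alpha-tubulin, fell by 1.57 ± 0.29 (adjusted p = 0.00126), Gm4312 by 1.55 ± 0.24 (0.000265), the histone gene H2ac19 by 1.44 ± 0.32 (0.00452) and Ppp2r3d by 1.29 ± 0.28 (0.00351). Another histone gene, H2ac23, fell at least 5.10-fold (adjusted p = 0.000296) to below the background limit on all adult arrays. Normexp gave smaller log2 changes, −0.99 for H2ac23 and 1.45 for Csprs, both below their bounds, and −0.61 for Ppp2r3d. Each of these 13 genes kept its call under every alternative run for it, and with the slide as a block or within the second slide the estimates were the same, because both stages lay on that slide.

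Probes named for lincRNAs rose at this step: 252 against 128 for lincRNA exons, 54 against 8 for human lincRNAs and 36 against 1 for mouse lincRNAs, in each family under every other scaling and without any 1 array (lincRNA exons 119 up and 114 down without adult replicate 1). Among ultraconserved elements 33 rose and 35 fell, but 36 rose and 25 fell after normexp, and 66 rose and 42 fell with the slide as a block. In all, 9662 features changed (25.9%), 4675 up and 4987 down, 7841 at least 2-fold. Noncoding calls numbered 480, 342 up (71.2%) and 138 down. The median log2 difference over all tested features was 0.168 at this step, against 0.454 for noncoding features. Within the second slide 13149 features were called, 743 of them noncoding (583 up, 160 down), and 12151 and 675 with the slide as a block. The balance over all features then turned to 53.9% and 53.5% up, and it was 52.0% up with normexp. Noncoding calls fell to 275 and 295 without neonatal replicates 2 and 3, and to 271 and 293 without adult replicates 1 and 3.

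**Figure D2:**
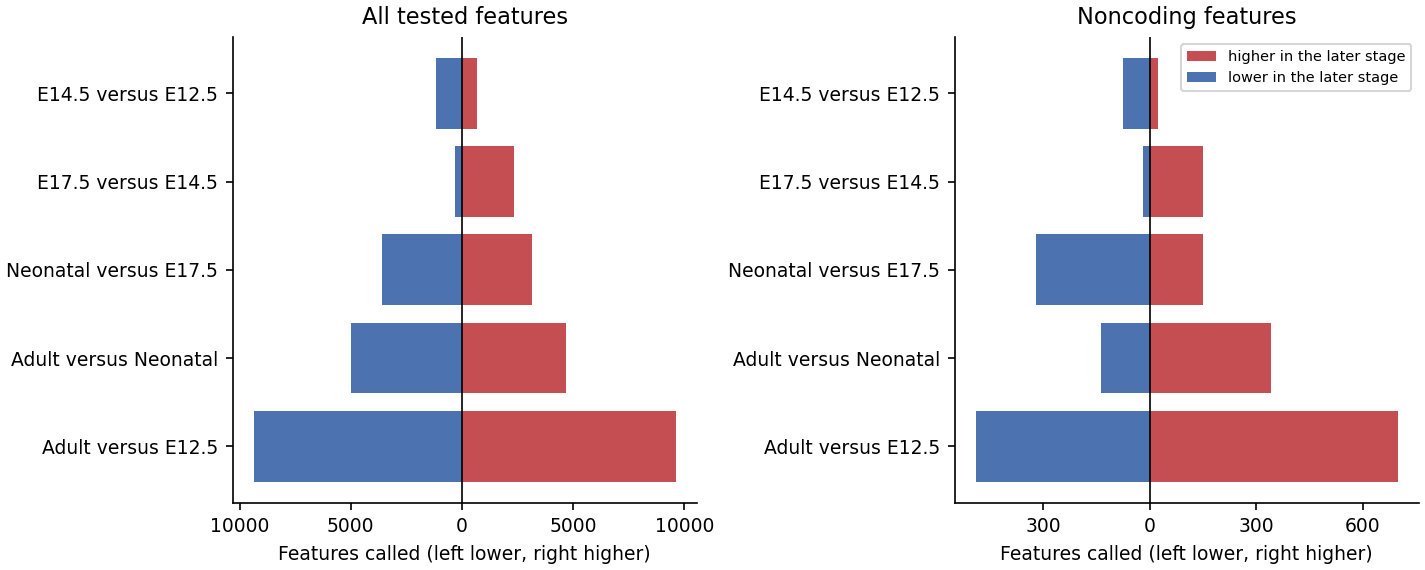
Number of features called at each step and between adult and E12.5 liver (horizontal axes; bars to the right, higher in the later stage, and to the left, lower), for all 37357 tested features and for the 2533 noncoding ones. At E17.5 against E14.5 most calls were upward (2352 of 2656; 73.3% after quantile normalization), and noncoding calls were mostly downward at birth (319 of 469; 66 of 110 with the slide as a block) and upward into the adult (342 of 480).

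Over the whole course, from E12.5 to adult liver, H2ac18 rose 30.6-fold (log2 change 4.93 ± 0.24, adjusted p = 1.09e-09), Gk 16.0-fold (4.0 ± 0.29, 8.15e-08) and Amy2a5 at least 41.6-fold (adjusted p = 1.59e-10 for the unbounded difference). B2m, the light chain of MHC class I molecules, rose by 2.68 ± 0.32 (adjusted p = 9.68e-06), Tmlhe, which starts carnitine synthesis, by 2.35 ± 0.29 (1.46e-05), and B020031M17Rik by 3.57 ± 0.68 (0.000601). Tfrc fell 10.5-fold (−3.39 ± 0.34, adjusted p = 1.8e-06), and H2ac23 fell at least 18.9-fold (adjusted p = 8.88e-07). Gm4312 fell by 2.90 ± 0.24 (2.59e-07), Tuba1b by 2.40 ± 0.29 (1.23e-05), H2ac19 by 2.14 ± 0.32 (8.3e-05), the ribosomal protein gene Rpl13a by 2.03 ± 0.23 (7.26e-06) and Ppp2r3d by 1.21 ± 0.28 (0.00223). Normexp gave 4.21 for Amy2a5 and 2.86 for Gk, 2.65 for B020031M17Rik, −2.39 for H2ac23 and −0.53 for Ppp2r3d, with the calls kept. Of these the H2ac23 and Amy2a5 values lay below their bounds. No slide held both stages. With the slide as a block the estimates were 4.82 for H2ac18, 3.91 for Gk, 2.01 for B2m, 1.48 for Tmlhe (adjusted p = 0.0188; range over its alternatives 1.01e-06 to 0.0188), −4.42 for Tfrc, −3.12 for Tuba1b, −3.19 for H2ac19 and −2.72 for Rpl13a, all called. The block ended the calls of B020031M17Rik (3.54, adjusted p = 0.054; range over its alternatives 6.81e-05 to 0.054) and Ppp2r3d (−0.80, adjusted p = 0.21; range 0.000523 to 0.21), as the slide was then estimated from E17.5 alone.

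In all, 18978 features differed between adult and E12.5 liver (50.8%), 9619 up and 9359 down, 16295 at least 2-fold. The balance turned to 46.2% up after quantile normalization and 41.8% up in the authors' table. Noncoding calls numbered 1188, 698 up (58.8%) and 490 down. Of noncoding features 293 were well above background on all adult arrays and no E12.5 array, against 86 the other way round, and of unclassified features 2452 against 1013. Adult arrays had 58.3% to 62.9% of noncontrol spots well above background, and E12.5 arrays 50.9% to 59.6%. Of the noncoding calls 46.0% were up in the authors' table (356 up, 418 down), and 480 up and 170 down with the slide as a block. The authors' table holds only probes well above background on at least 12 arrays. Its up shares are therefore over a different set of features, and its filter and scaling were not told apart. By family, 513 lincRNA exon probes rose and 387 fell, 120 and 62 human lincRNA probes, and 65 and 40 mouse lincRNA probes. The authors' table gave 285 and 334, 50 and 50, and 21 and 33, and the slide as a block 336 and 161, 89 and 5, and 55 and 4. The block left 11844 calls in all and 650 among noncoding features. Its slide term rests on the E17.5 arrays, of which replicate 1 had raised signals in dim probes. The files do not pair the lincRNA probes with genes. As examples chosen after their values were seen, MM9LINCRNAEXON10415-_P1 rose by 7.84 ± 0.39 (adjusted p = 1.56e-09), and MM9LINCRNAEXON10517+_P1 fell by 7.41 ± 0.22 (adjusted p = 1.52e-11). Among ultraconserved elements 75 probes rose and 84 fell, with 73 up and 64 down after normexp and 53 up and 40 down with the block; uc.136+ fell by 3.93 ± 0.27 (adjusted p = 3.41e-08).

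**Figure D3:**
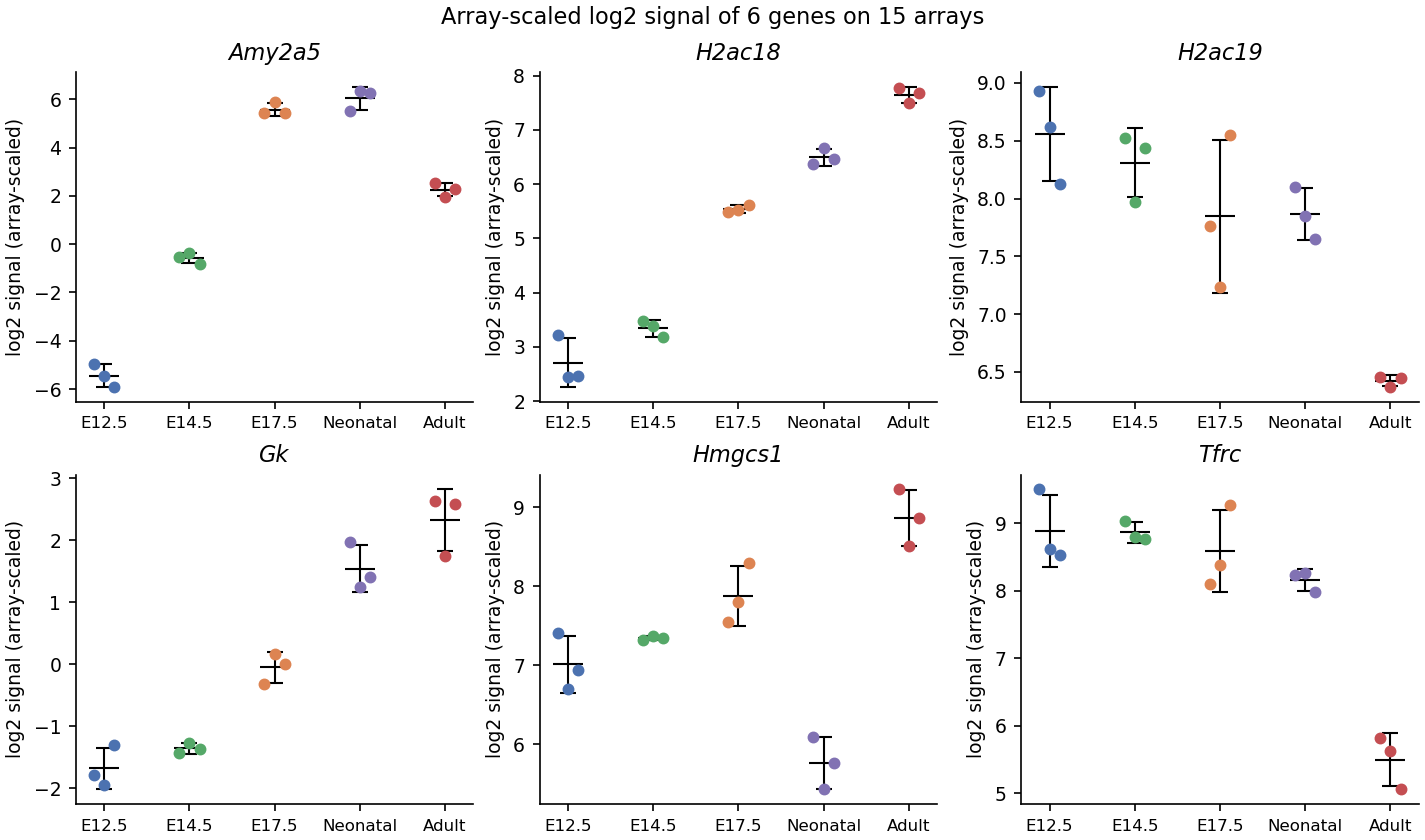
Array-scaled log2 signal (vertical axes) of Amy2a5, H2ac18, H2ac19, Gk, Hmgcs1 and Tfrc at the 5 stages (horizontal axes), with 1 point per array and bars for mean ± SD (n = 3). Hmgcs1 was lowest in neonatal liver (5.76) and highest in adult liver (8.86), and Tfrc stayed between 8.16 and 8.89 before its adult level of 5.50.

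Across all 5 stages, 22791 features (61.0%) differed in limma's F test, 21603 of them at least 2-fold between their highest and lowest stage means. The highest mean lay in the adult for 36.1%, at E12.5 for 22.3%, at E14.5 for 20.8%, in neonatal liver for 14.7% and at E17.5 for 6.10%. Probes named for human lincRNAs were highest in the adult in 45.9% and at E14.5 in 31.5% of cases, but in neonatal liver in 3.60%. For mouse lincRNAs both the adult and E14.5 took 36.8%, with 5.26% in neonatal liver. These shares are from the main setting alone and were not matched on signal. Human and mouse lincRNA probes were dimmer than the rest (median log2 signal −2.17 and −2.16, against −0.86 over all features). The median fall of these families at birth was also not seen with the slide as a block, as given above. Stage means rose at each of the 4 steps for 2281 features and fell at each for 1452, and among 1437 noncoding features for 161 and 51. With the slide as a block 15437 features differed. Of the 75 named genes tested, 42 differed in the F test.

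**Figure D4:**
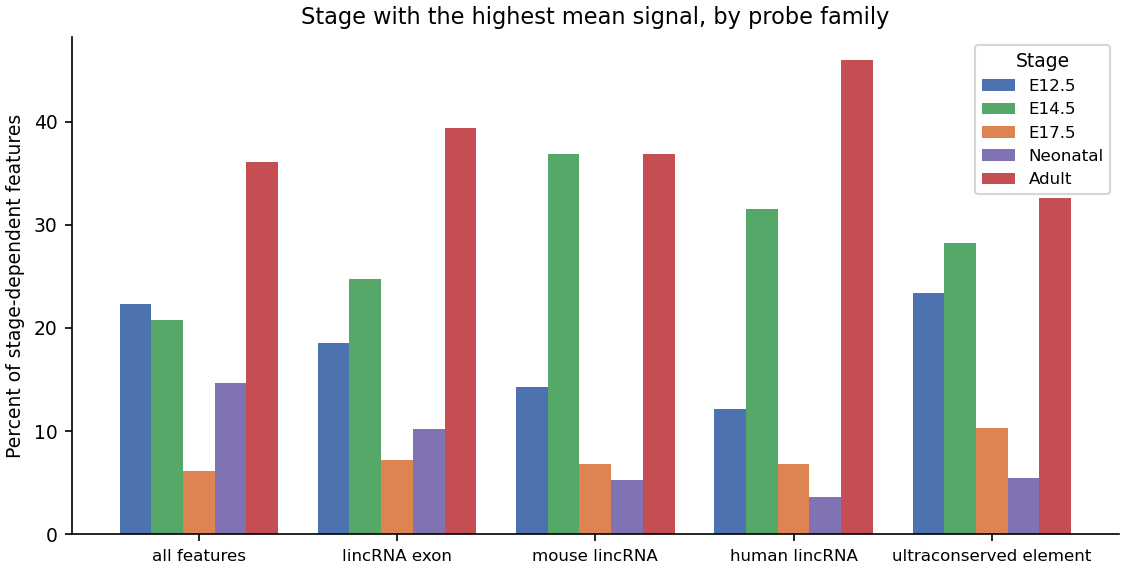
Percent of the features that differed among the stages and changed at least 2-fold (vertical axis) whose highest mean lay in each stage (colours), for all features and 4 probe families (horizontal axis). Human lincRNA probes peaked in the adult in 45.9% and in neonatal liver in 3.60% of cases. The shares are from the main setting alone and were not matched on signal.

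Noncoding features were dimmer than the rest (median log2 signal −1.74, against −0.86 over all features), so their calls were set against 10000 random sets of features matched on signal. For noncoding features these sets came from the other tested features, 34747 unclassified and 77 coding ones. Unclassified probes may themselves detect noncoding RNAs, so the sets do not stand for coding genes. All sets were drawn in the main setting alone, so the other values here have no matched range of their own. From neonatal to adult liver fewer noncoding features changed than in matched sets (18.9%, against a median of 24.6% and a 95% range of 22.9% to 26.1%), and more of the calls were up (71.2%, against 50.9%, range 47.2% to 54.6%; 55.7% without adult replicate 1). From E17.5 to neonatal liver 18.5% changed (matched 17.6%, range 16.2% to 19%), and 32.0% of the calls were up (matched 44.3%, range 40.0% to 48.8%; 40% with the slide as a block and 42.4% with the negative-control background). For ultraconserved elements that up share was 17.0%, against 42.9% (range 30.0% to 55.6%). Of the adult against E12.5 calls 58.8% were up (matched 53.3%, range 50.8% to 55.9%; 53.6% after quantile normalization, 46.0% in the authors' table and 73.85% with the block), on 46.9% called (matched 50.4%, range 48.6% to 52.2%). At E14.5 against E12.5 and at E17.5 against E14.5 the share called was within the matched range (3.87%, range 3.75% to 5.29%, and 6.63%, range 6.51% to 8.45%). The up share of the calls lay below its matched range at the first of these steps in the main setting (22.4%, matched 32.4%, range 24.4% to 40.8%), but it was 25.5% after quantile normalization, 38.3% with normexp, 34.3% in the authors' table, 33.3% with the block and 56.1% without E12.5 replicate 1. At the other step it lay within the range (89.3%, range 87.1% to 94.9%), and other scalings gave 65.2% to 93.05%. These percentiles describe the features of these arrays, which are not independent of each other.

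Of 35 gene lists with 661 genes, 4 had a member that was measured under a gene symbol here. The erythroid maturation list had Tfrc alone, which fell from neonatal to adult liver. The cholesterol synthesis list had Hmgcs1 alone, which fell at birth and rose into the adult. The exocrine pancreas list had Amy2a5 alone, which rose at the first 2 embryonic steps and fell into the adult. With 1 member, a p adjusted over the list alone is the unadjusted p, so these 3 lists add no test of their own. Only the housekeeping list had enough members for a set test, 7 of 15 (Actb, Gapdh, Tbp, Hprt, Ppia, B2m and Gusb), and limma's camera gave adjusted p = 0.908 at each of the 4 steps and 0.968 for adult against E12.5 (0.985 with an estimated correlation). Of 5 such tests 0 had an unadjusted p under 0.05. Its median changes at the 4 steps were −0.20, 0.07, 0.22 and −0.19, and −0.08 from E12.5 to adult. With the slide as a block they were −0.20, −0.17, −0.28, −0.19 and −0.97, within the first slide −0.20 and −0.17, and within the second −0.28 and −0.19. After quantile normalization the neonatal step turned to −0.09. Adjusted over all features as over the list alone, B2m rose from neonatal to adult liver (1.24 ± 0.32, adjusted p = 0.0107) and from E12.5, and Tbp, the TATA-binding protein, fell from E12.5 to adult (−0.85 ± 0.24, adjusted p = 0.0102), each under every scaling of the scanner values. Over that span Hprt was also called lower in every other scaling of the scanner values and with the block. Gusb was called lower there after quantile normalization and with the block. For Tbp the slide as a block gave −1.62 (adjusted p = 0.00248; range over its alternatives 0.00115 to 0.042). Hmgcs1 rose by 1.85 ± 0.28 from E12.5 to adult (adjusted p = 9.86e-05), a call lost with the slide as a block (1.23, adjusted p = 0.0572; range over its alternatives 5.23e-06 to 0.0572).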

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

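The tests of the offset and of the array's correlation with each stage and the fits without that array were set before their results were seen, the test of its position among the stages was chosen after results were seen, and the subtraction of the negative-control background after the arrays' quality values were seen.

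On E17.5 replicate 1, 55.8% of the 1200 negative-control spots were well above background, against 4.0% to 9.58% on the other 14 arrays, a signal in control spots that enter no comparison, and their median background-subtracted signal was 37.1 there and between −0.701 and 1.74 elsewhere. An additive offset on that array was tested on the 12588 probes not well above background elsewhere. Their median was 34.2, inside the 10th to 90th percentile of the negative-control spots (7.79 to 65.4), which met the rule set for an offset. On that array 52% of them passed as well above background. Their median lay inside that range on every other array too. The test shows that dim probes and control spots rose alike, and it cannot tell an offset from another cause that raises both. RNA wholly of another of the 5 stages on that array is argued against by its position after the median of the negative-control spots was subtracted. On axes from the mean of each other stage (0) to the E17.5 array on that stage's slide (1), the array lay at 0.681 or above. Those stages' own arrays lay at 0.361 or below. Each axis ends on 1 E17.5 array, and the test cannot exclude a mixture with RNA of another stage. A wrong label for an age outside these 5 stays open, since the earlier test was undecided (mean correlation 0.9446 with the other E17.5 arrays and 0.9436 with E14.5, a gap of 0.00093), and no biological explanation was tested.

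Without that array, E17.5 versus E14.5 gave more up than down calls among mouse lincRNA probes (7 up, 3 down) and human lincRNA probes (17 up, 6 down), as with it. E17.5 versus E14.5 gave 2376 calls in place of 2656, and neonatal versus E17.5 gave 4411 in place of 6747.

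Other divisions of the arrays were counted for each result. For each comparison of 2 stages there are 10 divisions into 3 and 3 arrays, too few for a share under 0.05, and 1 of the 10, the real one, gave as many calls: 1843, 2656, 6747, 9662 and 18978 in the order of the report, with 8, 17, 158, 0 and 0 calls as the highest of the others. For the F test over 5 stages, 1 of 100 divisions, the real one with 22791 features, gave as many, and the highest other gave 16561. A chance division is thus argued against, with 1 of 100 the smallest share that could be reached. The divisions did not keep the slides, so they cannot separate stage from slide.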

How the results depend on the processing

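The background set from negative-control probes, the fits within a slide and those without E17.5 replicate 1 throughout were chosen after the data were seen. Of 44 gene comparisons, 29 kept direction and call under every alternative run for them and 15 lost the call under at least 1. In 833 alternatives 761 were the same, 72 lost the call and 0 turned direction. The authors' table held 32 of the 44, and the threshold of 0.01 was applied to counts only. The following counts of calls moved by over 1.5 times, given as all features and then noncoding ones. The cause was not tested, except that a stricter threshold can only lower a count. Fewer stages in the fit moved counts both ways. Normexp gave 3004 and 167 at E14.5 versus E12.5. The authors' table gave 91 noncoding at E17.5 versus E14.5 and 774 at adult versus E12.5. With no filter on dim probes there were 1140 and 62 at E14.5 versus E12.5, and with only features well above background on all arrays 1516 and 73 at E17.5 versus E14.5 and 12175 and 610 at adult versus E12.5. Only the 2 stages compared gave 1116 and 53, 1297 and 62, and 2832 and 172 at the first 3 steps, and 743 noncoding at adult versus neonatal. An adjusted p below 0.01 left 750 and 39, 1132 and 56, 2829 and 178, and 5481 and 211 at the 4 steps. The slide as a block gave 153 noncoding at E14.5 versus E12.5, 2265 and 110 at neonatal versus E17.5, and 11844 and 650 at adult versus E12.5. The first slide alone gave 1410 and 64 at E17.5 versus E14.5, and the second 2196 and 111 at neonatal versus E17.5 and 743 noncoding at adult versus neonatal.

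Leaving out 1 array gave 673 to 2603 features and 32 to 164 noncoding ones at E14.5 versus E12.5, 1380 to 3288 and 81 to 263 at E17.5 versus E14.5, 3611 to 13309 and 210 to 1110 at neonatal versus E17.5, 6632 to 10447 and 271 to 535 at adult versus neonatal, and 16088 to 19591 and 978 to 1222 at adult versus E12.5. The F test gave 19817 to 26099, and 0 lists passed camera in any. The stages share replicate numbers, but these do not pair the arrays: 7 of 30 same-numbered pairs and 9 of 60 others had deviations correlated above 0.1, and 7 of 15 arrays correlated best with their own number. The replicate block gave 1617, 2659, 6936, 9889 and 19204 calls, 89, 172, 496, 501 and 1214 noncoding, and 22878 in the F test. Signal over background limited what was tested, to 2533 of 5369 noncoding features and 329 of 962 ultraconserved element probes.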

Other observations

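The gene groups here were drawn from the arrays' annotation before any gene's values were looked at and the strand and slide tests were set before their results, but the rule by which the strand result is read, its reliability check, the slide block on these groups and the background set from negative-control probes were chosen after results were seen. The 3 measured histone H2A genes, whose products package DNA, parted ways: from E12.5 to adult liver H2ac18 rose 30.6-fold, while H2ac19 fell by 2.14 ± 0.32 and H2ac23 fell at least 18.9-fold. Each gene was represented by 1 probe, and whether these probes tell the transcripts of the histone genes apart was not tested. The directions and calls held in each scaling and with the slide as a block, the sizes not (H2ac23 −2.39 with normexp, below its bound, and H2ac19 −3.19 with the block). The chemokine and immune surface group had 3 of 6 members called from neonatal to adult liver, all up (Ccl21b, Ccl21c and B2m), in each scaling of the scanner values, with 2 of 5 in the authors' table, which has no B2m. Ccl21b and Ccl21c were not told apart, so the 3 calls rest on fewer separate signals. Over all features 25.9% were called at this step. Of 13 genes of general cell machinery, 7 fell from E12.5 to adult liver, among them Nono (−0.89 ± 0.27, adjusted p = 0.0148), Ccdc82 (−1.35 ± 0.29, adjusted p = 0.00134) and Zfp131 (−1.15 ± 0.32, adjusted p = 0.00782), and Tmlhe and Vamp7 rose, the same genes in each scaling of the scanner values (2 up and 4 down of 9 in the authors' table). The same 7 fell with the slide as a block, but Vamp7 was not called and Mia3 rose instead; the group's median change was −0.70, and −1.35 with the block. Of the 15 genes spotted 20 times, 3 rose (Gk, B2m and Ldhal6b) and 5 fell over the same span, with a median of −0.58, below 0 in each scaling of the scanner values. The call of Ldhal6b was lost after quantile normalization, normexp and the other percentile. In the other scalings 6 or 7 fell, and with the slide as a block 3 rose and 7 fell, with a median of −1.06.

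Of 8 measured vomeronasal receptor genes, 2 rose (Vmn1r157, at least 3.49-fold, adjusted p = 0.000243, and Vmn1r111, at least 1.66-fold, 0.000181) and 5 fell from E12.5 to adult liver, among them Vmn1r187 (at least 7.56-fold, adjusted p = 0.000134), with 3 down after normexp, 6 down with the other percentile, and 0 up and 4 down of 5 in the authors' table. The 2 that rose shared the same value on each E12.5 array, so their adjusted p rests on no spread of their own at E12.5. Among those that fell, Vmn1r135, Vmn1r257 and Vmn1r259 had similar means (−1.07, −1.21 and −1.49 at E12.5, −2.55, −2.52 and −2.79 in adult liver). Whether their probes detect separate transcripts was not tested, so the calls may rest on fewer separate signals. With the slide as a block 0 of the 8 were called by limma, and the median turned from −1.30 to 0.21. That slide term was estimated from the E17.5 arrays, of which replicate 1 had raised signals in dim probes. For dim genes such as these it may therefore not be a slide effect alone. Of 4 measured germ line genes Tcstv1 rose by 2.54 ± 0.62 (adjusted p = 0.0035; well above background on 2 of 3 E12.5 arrays) and H2al2b fell by 1.60 ± 0.31 (adjusted p = 0.000693), and neither was called with the block. No added group passed camera (lowest adjusted p = 0.453, and adjusted p = 0.948 with an estimated correlation); of 20 such tests 2 had an unadjusted p under 0.05, 0.0475 for cell machinery at E14.5 versus E12.5 and 0.048 for the chemokine group at adult versus neonatal.

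E17.5 replicate 3 stood apart from replicates 1 and 2. On the axis from the mean of E14.5 (0) to that of neonatal liver (1) it lay at 0.565, against 0.305 and 0.275, and it is the 1 E17.5 array on the second slide. A slide effect as the whole cause was tested by correlating, across 23307 features, its difference from replicate 2 with the steps that lie within a slide. The correlations were −0.195 with E14.5 minus E12.5 and −0.252 with adult minus neonatal. These met the rule set for a slide effect, but values below 0 rather than near it make the test weak. An array nearer to neonatal liver could also give a value below 0 with adult minus neonatal. On component 2 the neonatal arrays lay between −129.92 and −114.43 and the adult arrays between 65.6 and 107.26. The test therefore does not separate slide from age. Its correlation with the step from E14.5 to neonatal liver was 0.403, but that step also crosses the slides and cannot separate age from slide, so later developmental age was left untested.

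Opposite-strand probes of the same lincRNA exon changed together only in part: over 526 pairs the slope of 1 strand's log2 change from E12.5 to adult on the other's was 0.21 (95% bootstrap interval 0.107 to 0.301), with r = 0.220 across pairs, which are not independent replicates, against 0.143 as the highest of 1000 random pairings. This was the comparison named beforehand; over all 20 fits, of 4 probe families in 5 comparisons, slopes ran from −0.173 to 0.277. Labelling that does not keep the strand was to give a slope above 0.7, and the rule first set for its absence, an interval wholly below 0.3, left the test undecided. After the result was seen that rule was replaced in 2 steps, by a slope below 0.3 and then by a slope below 0.3 with an interval below 0.7, and only under the replaced rules is a full loss of strand argued against. Reliability was 0.926, and of 124 pairs called on both strands 85 moved the same way and 39 opposite ways, so a smaller leak or transcription of both strands may remain.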
